A study of Mus musculus with 8 samples.

How the data were processed

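RNA from mouse spleen B cells was measured on 8 Affymetrix whole-transcript arrays, in 4 groups of 2 arrays whose replicates are labelled biological. Per the labels' protocols, B cells were enriched from spleen by depleting cells that carry CD43, RNA was taken with TRIzol and labelled with the WT PLUS kit. LMP1 cells and YFP control cells came from female (C57BL6 x BALBc)F1 mice, were treated with the cell-permeable recombinase TAT-Cre, and were sorted for their reporter after 2 days. Naive control cells and CD40-activated cells came from male C57BL/6J mice. The naive cells went directly into RNA preparation, and the activated cells were kept with an antibody against CD40 for 2 days. The arrays of LMP1 and YFP control were re-analysed from an earlier series and normalized together with the new ones.

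The values are log2 expression per probe set as deposited by the authors, who background-corrected, quantile-normalized and summarised the arrays by RMA with the oligo package, per the submitters' processing notes (versions not given). They carry 2 decimals. The table held 25349 probe sets, of which 22225 matched 1 gene symbol, 616 several and 2508 none. Probe sets with several or no symbols were left out of the comparisons. For the 640 genes with several probe sets the brightest over all arrays was used, which left 21515 genes. Symbols came from the platform's table, and a gene table of assembly GRCm38.p6 was used only for gene biotypes. Array medians lay between 5.52 and 5.68. With 2 arrays per group, the number of arrays limits the precision of every value.

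All 8 arrays were fitted in 1 model of 4 group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes at default settings), with 4 residual degrees of freedom and 5.75 prior degrees of freedom. P-values were two-sided and adjusted by Benjamini-Hochberg over all genes, and a gene passed at an adjusted p under 0.05. Genes past this threshold with a log2 change of at least 1 were counted as well. Comparisons were LMP1 with YFP control, CD40-activated with naive control, LMP1 with CD40-activated, the difference between the first pair of changes, and YFP control with naive control, which shows what separates the controls. Genes shared by the responses were counted against independence with one-sided Fisher's exact tests. Errors beside a log2 change are standard errors from the model, and errors beside a level are SD over 2 arrays.

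The comparisons, tests and 33 gene lists with 485 genes were fixed before the data were examined. Of these genes, 423 were measured and 62 were not analysed here. The lists were NF-kB targets and feedback, CD40 and TRAF signalling components, MHC class I presentation, MHC class II presentation, costimulatory ligands, coinhibitory ligands and receptors, adhesion molecules, cytokines and chemokines, chemokine and homing receptors, apoptosis regulators, cell cycle, tumour-associated antigens, MYC and ribosome biogenesis, glycolysis, cholesterol synthesis, unfolded protein response, interferon-stimulated genes, p53 targets, immediate-early and stress genes, B cell identity, resting B cell, germinal centre B cell, plasmablast, marginal zone and B1 cell, immunoglobulin constant regions, sex-linked genes and strain-dependent genes. Markers of other cells formed the lists T cell, NK cell, monocyte and macrophage, neutrophil, dendritic cell, and erythroid and platelet. Each list was tested with limma's camera at its preset correlation, with camera at an estimated correlation, and with fry, adjusted over the lists of a comparison. Members past the test were counted over all genes and, separately, adjusted over the list alone.

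Named genes were chosen by a rule fixed in advance. It took, per comparison, the 10 genes with the highest and the 10 with the lowest log2 change among those past the threshold whose arrays did not overlap between the groups (no overlap condition for the difference of changes). It added up to 4 members of each list with the largest change and up to 2 with the smallest, and every member of the costimulatory, coinhibitory, sex-linked and strain-dependent lists. Gene models without a settled name could be given as a count. Genes named outside this rule were chosen after their values were seen, and the text says so.

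The procedure was tested on simulated data of the same size. With changes of 0.5 log2 it found 0 of 67 genes, with 1 log2 it found 43 of 67, and with 2 log2 66 of 66. It called 7 of 21315 unchanged genes, and 0 of 21515 genes where nothing had been changed. Camera found the 1 shifted list and 0 others. Such data hold no correlation between genes and no group with a wider spread, so they cannot show false calls that arise from either. For comparisons that share arrays, 20 further draws with no change gave the correlation and covariance that the shared arrays alone produce.

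Alternatives were eBayes with trend and robust fitting, only the 2 groups compared, genes below the 25th percentile of mean level left out, each array's median subtracted, quantile normalization within each set of arrays, all probe sets, the mean of a gene's probe sets, array weights, the replicate number as a block, and each array left out in turn. Leaving out YFP control 2 and naive control 1 together was added after seeing the data, as were the list tests without these arrays and the list tests under quantile normalization within sets. Where an array was left out, the lone array of its group was assumed to vary like the others.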

Results

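Gene expression was measured in 4 groups of mouse spleen B cells with 2 arrays each: cells expressing LMP1, their YFP control, CD40-activated cells and naive control cells. LMP1, latent membrane protein 1 of Epstein-Barr virus, is a membrane protein that signals without a ligand through many of the adaptors that the receptor CD40 uses. The series was designed to compare each kind of activated cell with its control and the activated cells with each other. Replicates correlated across genes with r = 0.996 for LMP1, 0.993 for CD40-activated, 0.980 for naive control and 0.974 for YFP control. YFP control 1 and 2 were more than 1 log2 apart at 950 genes, the naive controls at 364, the CD40-activated arrays at 34 and the LMP1 arrays at 14.

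LMP1 cells were compared with YFP control cells to ask what LMP1 changed in cells of the same background, sex, treatment and sort. Of 13 measured ligands that costimulate T cells 7 rose in LMP1 cells, with Cd70 up by 3.94 ± 0.17 (log2 change, n = 2 arrays per group) and Cd80 and Tnfsf9 (4-1BB ligand) up by 3.78 ± 0.43 and 3.60 ± 0.26. The Cd70 level was 8.25 ± 0.11 (SD) in LMP1 cells and 4.31 ± 0.17 in YFP control, the latter below the median gene of its arrays. Of 12 genes of MHC class II presentation 10 fell, among them Ciita, the master transactivator of class II genes, by -2.70. Of 28 cell cycle genes 27 rose, of 17 genes of MYC and ribosome biogenesis 17, and of 14 glycolysis genes 13. These lists were called at the preset correlation, and with an estimated correlation no list had an adjusted p under 0.0841. The highest increase of all was that of the cell cycle inhibitor Cdkn1a, at 4.03 ± 0.16. The sphingosine phosphate receptor S1pr1, which guides lymphocytes out of lymphoid organs, fell by -4.29 ± 0.25.

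In all, 4995 of 21515 genes changed with LMP1, 3208 up and 1787 down, and 2693 of them by at least 1 log2. With only these 2 groups in the model the count was 3664. Beyond Cdkn1a, Cd70, Cd80 and Tnfsf9, the largest increases were those of Ebi3, a subunit of interleukin 27 and 35 (3.97), the potassium channel Kcnma1 (3.87), Tspan33 (3.79), the death receptor Tnfrsf10b (3.79), the actin bundler Fscn1 (3.70) and the survival gene Bcl2l1 (3.69). Kcnma1 was uneven, at 10.21 and 8.02 on the LMP1 arrays and 4.47 and 6.03 on the YFP controls. The largest decreases were those of Crisp3 (-6.21), Ifi214 (-5.77), Wfdc17 (-4.57), Tgfb3 (-4.39), Fcrla (-4.34), Ifi209 (-4.33), S1pr1, the IgM Fc receptor Fcmr (-4.29) and Mir5104 (-4.14), with 1 gene model without a settled name. Without YFP control 2, on which both were higher, Wfdc17 was at -3.66 and Mir5104 at -3.10.

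Of the 13 measured costimulatory ligands 7 rose and 0 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 3.41e-06; adjusted p = 0.0841 with an estimated correlation). Besides Cd70, Cd80 and Tnfsf9 these were Icam1 (2.65), Tnfsf4, the OX40 ligand (2.44), Slamf1 (1.53) and Cd40 (1.28). Cd86 (0.56), Tnfsf8 (0.40), Cd48 (0.27), Tnfsf14 (0.06), Icosl (0.01) and Tnfsf18 (-0.64) did not pass. Cd80 differed between the YFP controls, at 6.46 and 8.23, while both LMP1 arrays were above 11. Targets and feedback regulators of NF-kB rose for 17 of 25 members and fell for 1, or 18 and 2 adjusted over the list alone (adjusted p = 5.57e-10; adjusted p = 0.0841 with an estimated correlation), with Ebi3, Bcl2l1, Fas (2.93) and Tnfaip3 (2.89) in front. MHC class I presentation rose for 7 of 16 genes, 8 adjusted over the list alone, and fell for 0 (adjusted p = 0.00146; adjusted p = 0.303 with an estimated correlation), led by the immunoproteasome subunits Psmb9 (1.19) and Psmb8 (0.98). Without YFP control 2 the class I count was 4 of 16 (adjusted p = 0.0499), and the list's median differed by -0.41 between the YFP controls. Among 13 coinhibitory ligands and receptors 2 rose and 5 fell, the same adjusted over the list alone, with no call for the list (adjusted p = 0.307). Pvr (1.91) and Tnfrsf14 (1.28) rose, Havcr1 (-1.90), Vsir (-0.87), Btla (-0.71), Pdcd1lg2 (-0.70) and Lag3 (-0.57) fell, and Cd274, encoding PD-L1, was at 0.20 without passing.

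Of 28 cell cycle genes 27 rose, and 28 adjusted over the list alone (adjusted p = 6.83e-19; adjusted p = 0.154 with an estimated correlation), such as Ccnd2 (2.88), the ribonucleotide reductase subunit Rrm2 (2.86) and Cdc6 (2.81). All 17 genes of MYC and ribosome biogenesis rose, by either adjustment (adjusted p = 3.56e-15; adjusted p = 0.1 with an estimated correlation), with the spermidine synthase Srm at 2.57 and Cad at 2.34. Glycolysis genes rose for 13 of 14 members and for 14 adjusted over the list alone (adjusted p = 1.04e-10; adjusted p = 0.113 with an estimated correlation), including the lactate transporter Slc16a1 (2.68) and Hk2 (2.65). Cholesterol synthesis rose for 10 of 13 genes, 12 adjusted over the list alone (adjusted p = 1.59e-08; adjusted p = 0.0841 with an estimated correlation), with Lss at 2.46 and Fdps at 1.89. The unfolded protein response list had 11 of 15 members up, 12 adjusted over the list alone (adjusted p = 8.53e-06; adjusted p = 0.0841 with an estimated correlation). Its leading members were Asns (3.38), Atf3 (2.15) and Chac1 (1.94), which are targets of ATF4, while the splicing-regulated factor Xbp1 was at -0.34 without passing. For p53 targets 13 of 16 rose and 1 fell, or 13 and 2 adjusted over the list alone (adjusted p = 1.21e-07; adjusted p = 0.1 with an estimated correlation), among them Cdkn1a, Sesn2 (2.89) and Phlda3 (2.25).

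Class II presentation fell for 10 of 12 genes and rose for 0, by either adjustment (adjusted p = 1.59e-08; adjusted p = 0.154 with an estimated correlation), with H2-Ob at -3.23, H2-Oa at -2.07 and H2-Eb1 at -1.77. The protease Ctss (-0.06) and Ifi30 (-0.22) did not pass. B cell identity genes fell for 9 of 15 members, 10 adjusted over the list alone (adjusted p = 2.37e-06; adjusted p = 0.245 with an estimated correlation), including Fcrla and the inhibitory receptor Cd22 (-2.44), while Pax5 was at 0.03. Of 18 resting B cell genes 9 fell and 1 rose, or 13 and 1 adjusted over the list alone (adjusted p = 1.8e-04; adjusted p = 0.396 with an estimated correlation), with Cd55 (-2.87), Btg2 (-2.81) and Klf2 (-1.92). Chemokine and homing receptors fell for 7 of 12 genes and rose for 0, or 8 and 1 adjusted over the list alone (adjusted p = 3.39e-04; adjusted p = 0.1 with an estimated correlation), namely S1pr1, S1pr3 (-3.35), Cxcr4 (-2.93) and others. The marginal zone and B1 list had 5 of 12 genes down and 2 up, or 7 and 2 adjusted over the list alone (adjusted p = 0.00179; adjusted p = 0.1 with an estimated correlation), with Plac8 at -3.97 and Bhlhe41 at -2.87. Interferon-stimulated genes fell for 9 of 18 members and rose for 2, or 11 and 3 adjusted over the list alone (adjusted p = 0.00179; adjusted p = 0.296 with an estimated correlation), such as Rtp4 (-2.35) and Irf7 (-1.86). The constant region genes Ighg3 (-1.56) and Ighm (-1.28) both fell, by either adjustment (adjusted p = 0.032; adjusted p = 0.213 with an estimated correlation).

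Several lists held members that moved apart. Cytokines and chemokines rose for 8 of 25 genes and fell for 3, or 8 and 4 adjusted over the list alone, with a list median of -0.02, a mean of 0.51 and an upward test that did not pass (adjusted p = 0.147). Without YFP control 2 that test passed (adjusted p = 0.0401). The chemokines Cxcl9 (3.34), Cxcl10 (3.26) and Ccl22 (2.89) led it. Apoptosis regulators rose for 8 of 17 genes and fell for 2, by either adjustment (adjusted p = 0.0117; adjusted p = 0.152 with an estimated correlation), a call that was lost without YFP control 2 (adjusted p = 0.131), with dim genes left out (adjusted p = 0.0717) and with quantile normalization within each set (adjusted p = 0.2). The rising members included the survival gene Bcl2l1 and the death receptors Tnfrsf10b and Fas, and the pro-apoptotic Bcl2l11 fell (-1.19). Of 20 tumour-associated antigens 7 rose and 0 fell, or 7 and 1 adjusted over the list alone, with a median of -0.02, a mean of 0.57 and an upward test that did not pass (adjusted p = 0.082). Its members Birc5 (2.97), Hmmr (2.40) and Ttk (2.18) also act in mitosis, and Epha2 (2.30) is a receptor tyrosine kinase.

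Further lists gave no call. CD40 and TRAF signalling components had 4 of 13 up and 3 down, the same adjusted over the list alone (adjusted p = 0.412), with Traf1 at 2.08 and Traf5 at -1.73. Adhesion molecules had 4 of 14 up and 3 down, or 4 and 4 adjusted over the list alone (adjusted p = 0.979), with Cd44 at 2.09 and Itgb7 at -2.66. Immediate-early and stress genes had 6 of 19 up and 3 down, or 8 and 4 adjusted over the list alone (adjusted p = 0.149). Jun, the first of them, was at 2.29 ± 0.73, with YFP controls at 8.78 and 5.95, and at 0.88 without passing when YFP control 2 was left out (adjusted p = 0.24). Germinal centre genes had 3 of 12 up and 3 down, or 4 and 5 adjusted over the list alone, with a median of -0.41, a mean of 0.07 and a downward test that did not pass (adjusted p = 0.661). Plasmablast genes had 2 of 14 up and 3 down, by either adjustment (adjusted p = 0.545), with Jchain at -3.47.

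Markers of other cells mostly did not pass between LMP1 and YFP control. The T cell list had 1 of 9 members down, Cd3g (-1.13), by either adjustment, and its median was 0.03 with a downward mean of -0.14 and a downward test (adjusted p = 0.672). With YFP control 2 left out, 0 T cell genes were down and 1 up, and the test turned upward without passing (adjusted p = 0.904). NK cell (0 of 9; adjusted p = 0.43), neutrophil (0 of 9; adjusted p = 0.381) and erythroid and platelet markers (0 of 5; adjusted p = 0.299) held no changed gene, by either adjustment. Monocyte and macrophage markers had 2 of 12 down by either adjustment, Adgre1 (-2.02) and Lyz2 (-1.91; adjusted p for the list = 0.147). Dendritic cell markers had 2 of 8 up, Flt3 (2.99) and Zbtb46 (1.79), and 1 further down adjusted over the list alone (adjusted p for the list = 0.375). None of the 4 sex-linked genes changed (adjusted p for the list = 0.641), and of the strain-dependent genes H2-Ea fell by -2.17 and Nnt was at 0.19 (adjusted p for the list = 0.241). The count of changed genes was 2647 without LMP1 array 1 and 2754 without LMP1 array 2. With quantile normalization within each set of arrays the directions were more even, with 2480 genes up and 2282 down (52.1% up against 64.2%), and with array medians subtracted 70% were up.

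**Figure D1:**
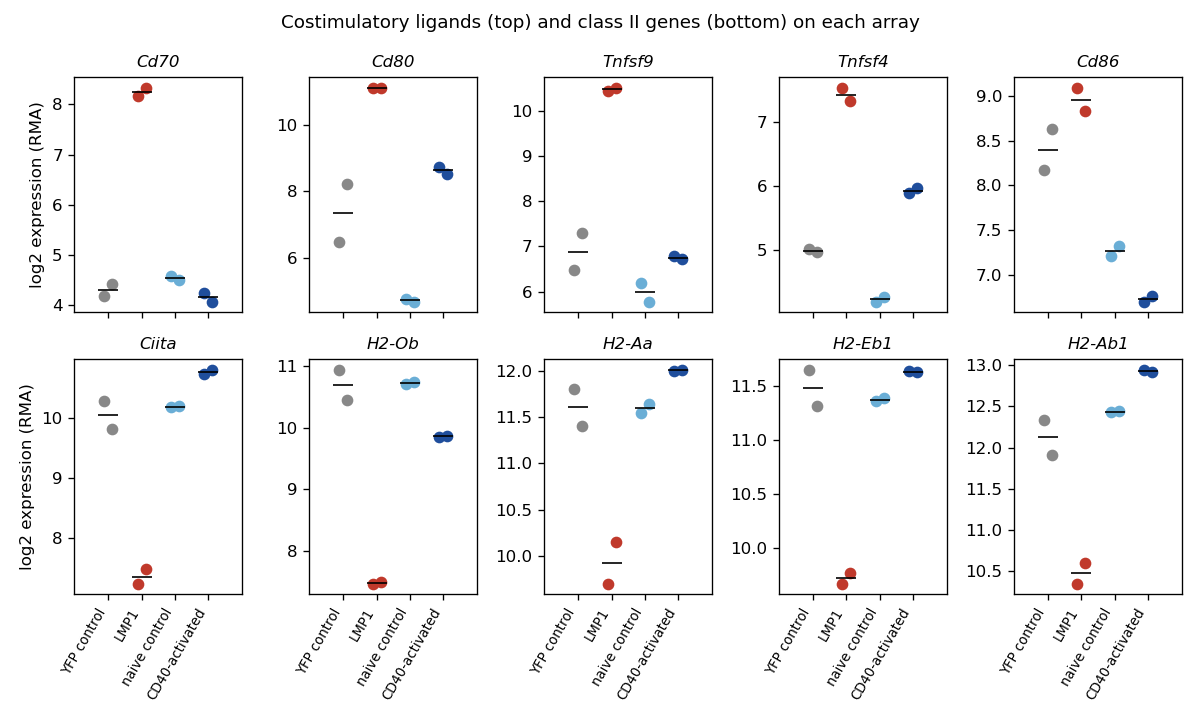
Log2 expression (RMA) of 5 costimulatory ligands and 5 class II genes on each array, with points for arrays and lines for group means of 2 arrays, and y axes that do not start at 0. Both LMP1 arrays lie above all others for Cd70 and Tnfsf9 and below all others for Ciita and H2-Ob.

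CD40-activated cells were compared with naive control cells to ask what activation through CD40 changed, with 2 days of culture going along with the antibody. The chemokine gene Ccl22, which attracts T cells, rose by 4.96 ± 0.35 (n = 2 arrays per group; naive level 5.10, below the median gene of its arrays) and Cd80 rose by 3.94 ± 0.43. Of 28 cell cycle genes 25 rose, and of 13 cholesterol synthesis genes 12. Of 19 immediate-early and stress genes 14 fell, with the heat shock gene Hspa1b down by -6.80 ± 0.37 and Fos and Jun down by -4.33 and -4.15. These lists were called at the preset correlation, and with an estimated correlation no list had an adjusted p under 0.0902. Of 12 class II genes 2 rose and 1 fell, with an upward call (adjusted p = 0.0352; adjusted p = 0.561 with an estimated correlation), and Ciita, chosen here after its values were seen, was at 0.58 without passing. YFP control cells, cultured for 2 days without the antibody, differed from naive cells by similar amounts for Ccl22 (5.18), Hspa1b (-7.00) and Fos (-4.27), and by 2.64 for Cd80 (YFP control 2 higher than YFP control 1 by 1.77). Of the cell cycle genes 14 of 28 were also higher in YFP control than in naive control, with a list median of 0.76 against 1.69 with CD40 activation. Cholesterol synthesis genes were higher for 9 of 13, with a median of 1.32 against 2.175. Strain, sex, TAT-Cre and sort differed there too.

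In this comparison 3803 genes changed, 2373 up and 1430 down, and 1793 of them by at least 1 log2. The other largest increases were those of the inhibitory receptor Lilrb4a (4.95), Mreg (4.95), the aryl hydrocarbon receptor Ahr (3.96), Zc3h12c (3.91), Fcrl5 (3.87), Ppfibp2 (3.76), S1pr3 (3.71) and Fam167a (3.65). The other largest decreases were those of Hspa1a (-6.51), the red cell anion exchanger Slc4a1 (-4.90), Ctse (-4.45), Neurl3 (-4.33), Snora30 (-3.91) and the erythroid gene Ermap (-3.82), with 1 gene model without a settled name. Without naive control 1, on which these 6 were higher, Hspa1b was at -6.17, Hspa1a at -5.39, Slc4a1 at -4.02, Ctse at -3.71, Fos at -3.67 and Ermap at -3.05.

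Of 28 cell cycle genes 25 rose, 26 adjusted over the list alone (adjusted p = 1.69e-18; adjusted p = 0.212 with an estimated correlation), such as Top2a (2.59) and Bub1 (2.50). Cholesterol synthesis rose for 12 of 13 genes by either adjustment (adjusted p = 1.37e-15; adjusted p = 0.0902 with an estimated correlation), with Cyp51 at 2.99, Sqle at 2.70 and Hmgcs1 at 2.69. MYC and ribosome biogenesis rose for 14 of 17 genes by either adjustment (adjusted p = 6.3e-10; adjusted p = 0.2 with an estimated correlation), with Srm at 2.12, while Myc itself was at 0.08. NF-kB targets rose for 11 of 25 genes and fell for 0, by either adjustment (adjusted p = 1.09e-05; adjusted p = 0.2 with an estimated correlation), with Ccl22, Plek (1.74) and Traf1 (1.68). Targets of p53 rose for 7 of 16 genes and fell for 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.0062; adjusted p = 0.314 with an estimated correlation). Glycolysis (6 of 14 up and 1 down; 7 and 1 adjusted over the list alone) and the unfolded protein response (7 of 15 up and 1 down, by either adjustment) were called upward at adjusted p = 0.0135 and 0.0313. Those became adjusted p = 0.512 and adjusted p = 0.236 with an estimated correlation, 0.216 and 0.229 with quantile normalization within each set, and 0.0724 and 0.106 with dim genes left out. Without naive control 1 the unfolded protein response count was 2 of 15 up (adjusted p = 0.0233).

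Costimulatory ligands rose for 5 of 13 genes and fell for 1, or 6 and 2 adjusted over the list alone, without a call for the list (adjusted p = 0.103). Cd80, Tnfsf4 (1.70), Icam1 (1.05), Cd40 (0.99) and Cd48 (0.56) rose, Tnfsf8 fell (-1.08), and Tnfsf9 (0.77), Cd86 (-0.54) and Cd70 (-0.40) did not pass. Class II presentation had 2 of 12 genes up, Ifi30 (1.19) and Lgmn (1.00), and 1 down, H2-Ob (-0.87), or 7 and 1 adjusted over the list alone, and 7 and 2 without YFP control 2. Its upward call (adjusted p = 0.0352; adjusted p = 0.561 with an estimated correlation) was lost when array medians were subtracted (adjusted p = 0.0521), with quantile normalization within each set (adjusted p = 0.23) and with dim genes left out (adjusted p = 0.106). Havcr1 (2.79) and Cd274 (0.97) rose among the coinhibitory genes, and Vsir (-1.87), Ctla4 (-1.16), Fasl (-1.15) and Tnfrsf14 (-0.90) fell. S1pr3 and Ccr6 (2.53) rose and Cxcr4 (-2.48) fell among the homing receptors.

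Immediate-early and stress genes fell for 14 of 19 members and rose for 1, or 15 and 1 adjusted over the list alone (adjusted p = 9.38e-10; adjusted p = 0.207 with an estimated correlation). Interferon-stimulated genes fell for 11 of 18 and rose for 0, by either adjustment (adjusted p = 2.77e-07; adjusted p = 0.2 with an estimated correlation), with Rsad2 at -3.06 and Irf7 at -2.04. Resting B cell genes fell for 10 of 18 and rose for 0, or 11 and 2 adjusted over the list alone (adjusted p = 5.63e-05; adjusted p = 0.415 with an estimated correlation), with Klf2 at -3.03, and 5 fell without naive control 1. All 9 T cell genes fell, by either adjustment (adjusted p = 1.92e-11; adjusted p = 0.2 with an estimated correlation), with Cd3g at -3.63 and Cd3e at -3.28. NK cell markers fell for 7 of 9 genes, 8 adjusted over the list alone (adjusted p = 5.77e-09; adjusted p = 0.2 with an estimated correlation), with Gzma at -3.40. Erythroid and platelet markers fell for 3 of 5 genes, 4 adjusted over the list alone (adjusted p = 2.43e-04; adjusted p = 0.2 with an estimated correlation). The count of changed genes was 1592 without CD40-activated array 1, 1576 without array 2, and 7146 without YFP control 2 and naive control 1, an alternative chosen after seeing the data. Subtracting array medians moved the median change of all genes from -0.05 to 0.06, a shift over 0.1, and gave 2808 genes up and 973 down (74.3% up against 62.4%). Quantile normalization within each set gave 1751 up and 1579 down (52.6% up).

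**Figure D2:**
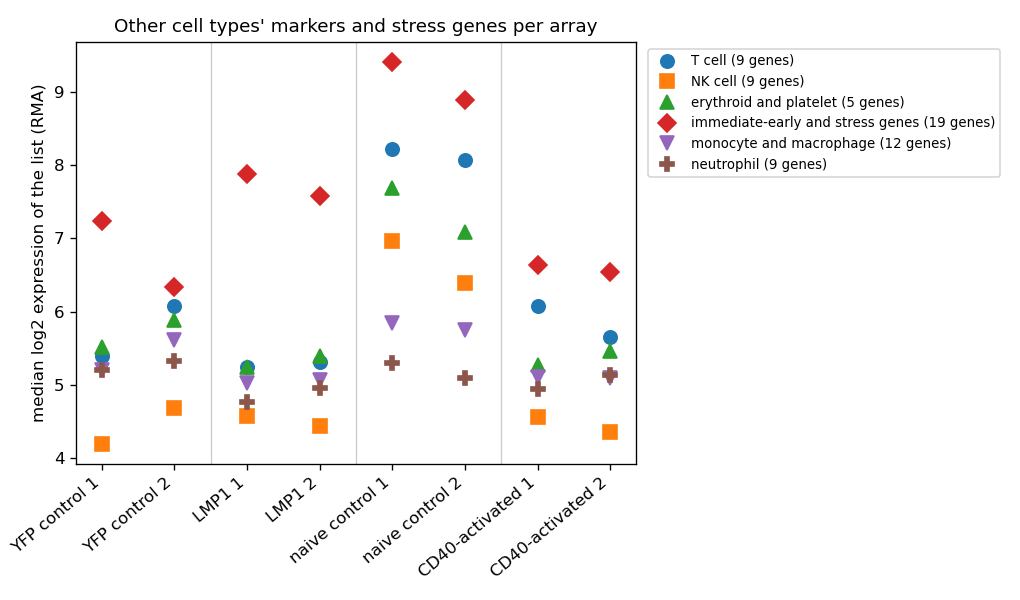
Median log2 expression (RMA) of 5 lists of other cells' markers and of the immediate-early and stress genes on each array, 1 point per list and array. The T cell list lies at 8.22 and 8.07 on the naive control arrays and between 5.25 and 6.08 on the other arrays.

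**Figure D3:**
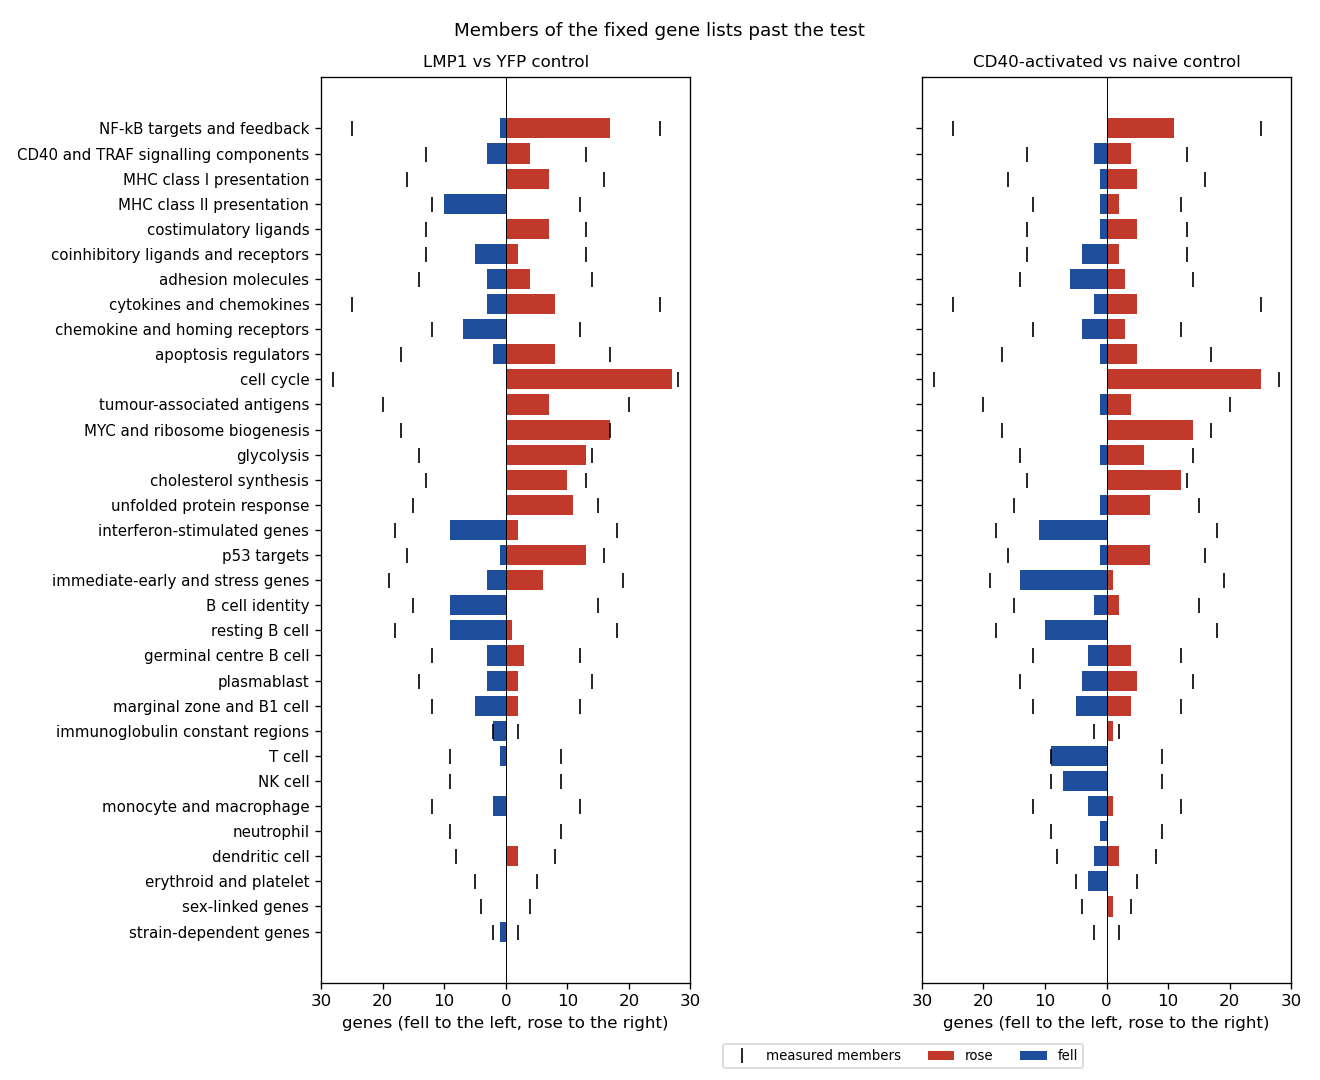
Number of members of each of the 33 gene lists that rose (right) or fell (left) with an adjusted p under 0.05, for both activated groups against their controls, with ticks at the number of measured members. Cell cycle genes rose for 27 and 25 of 28, and class II genes fell for 10 and 1 of 12.

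The changes with LMP1 and with CD40 activation were set against each other to ask how far both involved the same genes. No array enters both comparisons, but their calls share 1 spread per gene, and genes are not independent of each other. Expected counts and p-values are therefore descriptive. Genes higher in both numbered 1442, against 353.8 expected of independent responses (one-sided Fisher's exact test, log10 of p = -688), and genes lower in both 377, against 118.8 (p = 5.86e-101). Genes up with LMP1 and down with CD40 activation numbered 76, against 213.2 expected, and genes down with LMP1 and up with CD40 activation 153, against 197.1. The split by direction depended on the scaling: 930 genes were higher and 670 lower in both with quantile normalization within each set, and 1656 and 278 with array medians subtracted. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.436. The same-direction total of 1819 was 1084 and 1102 without LMP1 array 1 or 2, 881 and 898 without CD40-activated array 1 or 2, and 2867 without YFP control 2 and naive control 1.

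**Figure D4:**
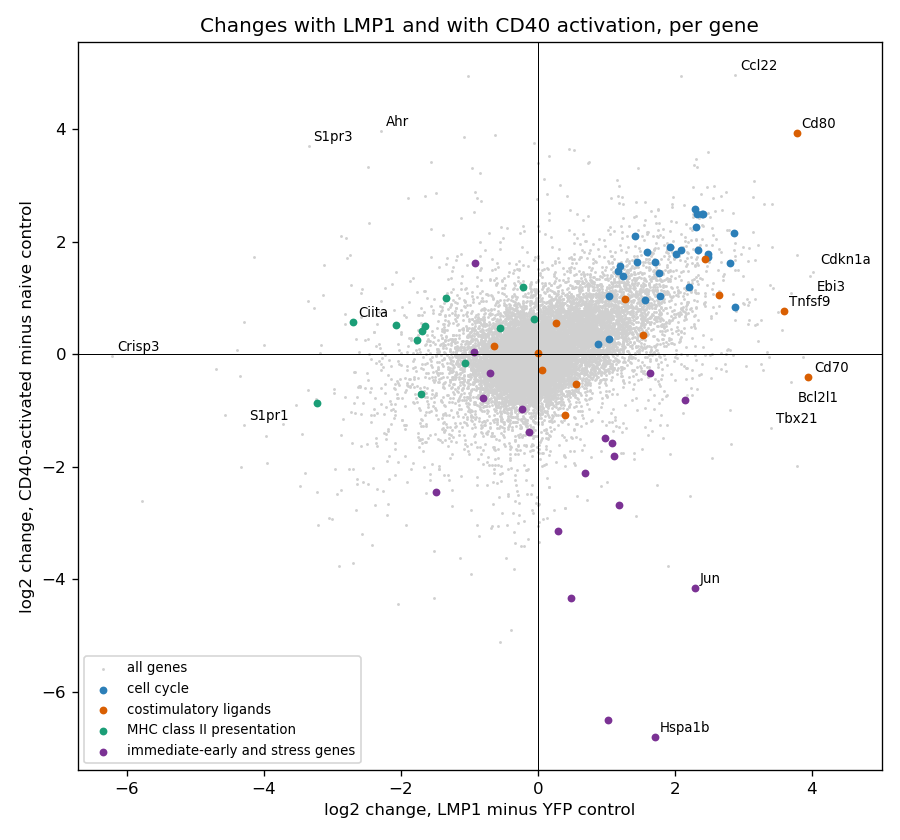
Log2 change with LMP1 against YFP control (x axis) and with CD40 activation against naive control (y axis), 1 point per gene, with 4 gene lists coloured. Cell cycle genes lie up in both directions, Cd80 is high on both axes at 3.78 and 3.94, and Cd70 is high only on the x axis at 3.94 against -0.40.

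The difference of these changes tested which genes responded otherwise to LMP1 than to CD40 activation, each against its own control. YFP control cells were cultured for 2 days and naive cells were not, and strain, sex, TAT-Cre and sort differed too, so the difference also holds what separates the controls. Part of this are markers of T, NK and red cells, which were higher in naive control than in YFP control. Of 13 costimulatory ligands 6 were higher in the LMP1 response, and of 12 class II genes 9 were lower. Both lists were called at the preset correlation, and with an estimated correlation no list had an adjusted p under 0.165. Cd70 differed by 4.34, Tnfsf9 by 2.83 and Tnfsf8 by 1.48, whereas Cd80 did not pass at -0.16. The Cd80 value depends on YFP controls that lay 1.77 apart, with YFP control 2 higher. Ciita differed by -3.28 and H2-Oa by -2.59. The widest differences in each direction were those of Hspa1b (8.51 ± 0.52), which rose by 1.71 with LMP1 and fell with CD40 activation, and S1pr3 (-7.06 ± 0.28), which fell with LMP1 and rose with CD40 activation. Between YFP control and naive control these genes differed by -7.00 and 3.72.

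The difference passed for 1790 genes, 903 higher and 887 lower with LMP1, and for 1608 of them by at least 1 log2. Others at the top were Hspa1a (7.53), Jun (6.44), Tspan33 (5.78), the carbonic anhydrase Car2 (5.67), Fos (4.82), Atp8b4 (4.74), the transcription factor Tbx21 (4.72) and Slc4a1 (4.52), with 1 gene model. Slc4a1 stood on the erythroid and platelet list, which was higher for 2 of 5 genes and lower for 0 (camera adjusted p = 0.00441, without a call at an estimated correlation). YFP control was lower than naive control for 3 of these 5 genes, and with LMP1 against YFP control 0 of them changed. At the bottom stood Ahr (-6.26), Crisp3 (-6.19), Lilrb4a (-5.97), Mir5104 (-5.87), the prostaglandin D synthase Hpgds (-5.82), Bhlhe41 (-4.98), Ms4a7 (-4.98), Fcrl5 (-4.94) and the endosomal receptor Tlr7 (-4.87). Costimulatory ligands were higher for 6 of 13 genes and lower for 0, or 7 and 0 adjusted over the list alone (adjusted p = 3.49e-04; adjusted p = 0.165 with an estimated correlation). Class II presentation was lower for 9 of 12 and higher for 0, or 10 and 0 adjusted over the list alone (adjusted p = 4.84e-13; adjusted p = 0.165 with an estimated correlation). B cell identity was lower for 7 of 15 and higher for 1, or 9 and 1 adjusted over the list alone (adjusted p = 2.41e-07; adjusted p = 0.187 with an estimated correlation), with Fcrla at -3.96 and Cd22 at -2.35, and 11 were lower without YFP control 2. Glycolysis was higher for 6 of 14 genes, 10 adjusted over the list alone (adjusted p = 5.32e-06; adjusted p = 0.185 with an estimated correlation). Cholesterol synthesis was lower for 8 of 13 genes by either adjustment (adjusted p = 1.94e-05; adjusted p = 0.165 with an estimated correlation), with Cyp51 at -1.81. The same list was higher in YFP control than in naive control for 9 of 13 genes (adjusted p = 1.19e-07; adjusted p = 0.337 with an estimated correlation). Directly in LMP1 against CD40-activated cells 4 were higher and 0 lower, by either adjustment, without a call (adjusted p = 0.234). For cell cycle genes the list's test did not pass (adjusted p = 0.0947), with Ccnd2 (2.04) and Aurka (1.00) higher and 0 lower, or 1 and 0 adjusted over the list alone.

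Stress genes were higher in the LMP1 response for 12 of 19 members and lower for 1, or 15 and 2 adjusted over the list alone (adjusted p = 1.46e-09; adjusted p = 0.165 with an estimated correlation). The list gave no call with LMP1 against YFP control (adjusted p = 0.149), and YFP control was lower than the uncultured naive control for 11 of its 19 genes and higher for 3 (adjusted p = 3.55e-05; adjusted p = 0.569 with an estimated correlation). Directly in LMP1 against CD40-activated cells, both cultured, 8 were higher and 1 lower, or 9 and 1 adjusted over the list alone (adjusted p = 1.90e-04; adjusted p = 0.324 with an estimated correlation). T cell markers moved with them, higher for 9 of 9 by either adjustment (adjusted p = 1.07e-10; adjusted p = 0.165 with an estimated correlation), as did NK cell markers for 7 of 9 by either adjustment (adjusted p = 6.24e-08; adjusted p = 0.165 with an estimated correlation). With LMP1 against YFP control, however, 0 T cell and 0 NK cell genes rose. YFP control was lower than naive control for 9 of 9 T cell and 8 of 9 NK cell genes. NF-kB targets were higher for 8 of 25 and lower for 2, or 10 and 3 adjusted over the list alone (adjusted p = 0.00281; adjusted p = 0.185 with an estimated correlation), a call lost without YFP control 2 (adjusted p = 0.0677), and 5 were higher without naive control 1. Jun was at 5.03 without YFP control 2. Bcl2l1 (4.19) and Ebi3 (2.59) were higher and Ccl22 lower (-2.07). The number of genes was 4199 without YFP control 1, 710 and 715 without LMP1 array 1 or 2, 728 and 707 without CD40-activated array 1 or 2, and 3543 without YFP control 2 and naive control 1.

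LMP1 cells were compared directly with CD40-activated cells to ask how both kinds of activated cell differ, although strain, sex, TAT-Cre, sorting and array set went along with the group. Cd70 was higher in LMP1 cells by 4.09 ± 0.17 (n = 2 arrays per group), at a level of 8.25 ± 0.11 (SD) against 4.16 ± 0.12, the latter below the median gene of its arrays. Tnfsf9 was higher by 3.73, Cd80 by 2.48 and Cd86 by 2.23. Cd80, however, rose by similar amounts in both responses and was also higher in YFP control than in naive control. Cd86 did not pass in either response. Ciita was lower by -3.42 and H2-Ab1 by -2.46. Tbx21, encoding T-bet, was higher by 4.46 ± 0.19, and Myof and the interleukin 9 receptor Il9r were lower by -4.29 and -4.38. The sex-linked genes followed the sexes in the labels, with Xist higher by 6.97 and Eif2s3y (-4.76), Kdm5d (-4.57) and Uty (-4.33) lower in cells of female mice (list adjusted p = 0.00194; adjusted p = 0.224 with an estimated correlation). H2-Ea, a class II gene that C57BL/6 mice do not transcribe, was higher by 5.38, and Nnt was at 0.19 (list adjusted p = 0.00867; adjusted p = 0.217 with an estimated correlation).

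Here 3191 genes passed, 2078 higher and 1113 lower in LMP1 cells, and 1642 of them by at least 1 log2. Further genes at the top were Kcnma1 (4.53), the telomerase RNA Terc (4.15), Cth (4.04), Gbp2b (4.02), Jun (3.79) and BC064078 (3.79). At the bottom were Snord61 (-6.18), Lilrb4a (-4.63), Snord110 (-4.36), Snord58b (-4.21) and the Y RNA gene Rny1 (-4.09). Costimulatory ligands were higher for 7 of 13 genes and lower for 1, or 8 and 1 adjusted over the list alone (adjusted p = 7.88e-06; adjusted p = 0.178 with an estimated correlation), the lower one being Icosl (-1.15). Class II presentation was lower for 10 of 12 genes, 11 adjusted over the list alone (adjusted p = 4.01e-14; adjusted p = 0.178 with an estimated correlation). Cell cycle genes were higher for 17 of 28, 24 adjusted over the list alone (adjusted p = 1.8e-12; adjusted p = 0.273 with an estimated correlation), with Ccnd2 at 2.78. Of these 28 genes 14 were also higher in YFP control than in naive control, and the difference of changes gave no call for the list. MYC and ribosome biogenesis was higher for 9 of 17, 11 adjusted over the list alone (adjusted p = 9.9e-08; adjusted p = 0.209 with an estimated correlation), with Myc at 1.48. Glycolysis was higher for 9 of 14, 10 adjusted over the list alone (adjusted p = 7.53e-08; adjusted p = 0.207 with an estimated correlation). B cell identity was lower for 8 of 15, 9 adjusted over the list alone (adjusted p = 5.82e-06; adjusted p = 0.293 with an estimated correlation). Homing receptors were lower for 6 of 12 and higher for 1, or 8 and 1 adjusted over the list alone (adjusted p = 9.31e-05; adjusted p = 0.178 with an estimated correlation), with S1pr3 at -3.33 and S1pr1 at -3.12.

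Among cytokines and chemokines 6 of 25 were higher and 1 lower, or 7 and 1 adjusted over the list alone (adjusted p = 0.0257; adjusted p = 0.523 with an estimated correlation), a call lost without naive control 1 (adjusted p = 0.0683). Cxcl9 (3.68) and Cxcl10 (3.48) were higher, and Ltb, a subunit of lymphotoxin, was lower (-3.19). T cell markers did not pass for any of 9 genes by either adjustment (adjusted p = 0.204). Of the genes that differed directly, 1128 (35.3%) differed the same way between YFP control and naive control. These comparisons share no array, but their calls share 1 spread per gene, so expected counts and p-values are descriptive here too. In both, 843 were higher (227.2 expected) and 285 lower (84.5 expected; one-sided Fisher's exact p = 5.69e-81). In opposite directions, 80 were higher directly and lower in YFP control (157.8 expected), and 143 lower directly and higher in YFP control (121.7 expected; one-sided Fisher's exact p = 0.0217). The direct count was 1275 and 1354 without LMP1 array 1 or 2, 1469 and 1279 without CD40-activated array 1 or 2, 6751 with array weights, and 6360 both with only the 2 groups and without YFP control 2 and naive control 1.

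The control groups were compared to show what separated the sets before LMP1 or CD40 activation. YFP control cells, cultured and from female hybrid mice, had higher H2-Ea (7.45 ± 0.16), Xist (7.12), Ccl22 (5.18), Cox7b (5.13), Crisp3 (4.47), Mpc1 (3.73), S1pr3 (3.72), Pla2g10os (3.72), Tgfb3 (3.65) and Wfdc17 (3.58) than naive cells. Crisp3, Tgfb3 and Wfdc17 were also among the largest decreases with LMP1. Both comparisons use the YFP arrays, with opposite sign, so high values on these arrays alone would place a gene in both. Among the lowest were the small nucleolar RNA genes Snord61 (-7.52), Snord58b (-7.17), Snord1b (-6.32), Snord110 (-6.00), Snord72 (-5.99), Snord70 (-5.63) and Snord73a (-5.16), with Hspa1b (-7.00), Hspa1a (-6.92) and Eif2s3y (-5.14). Without YFP control 2 the values were -6.16 for Snord61, -6.20 for Snord58b, -5.33 for Snord1b, -5.12 for Snord110, -5.09 for Snord72, -4.86 for Snord70, 2.67 for Wfdc17 and 4.57 for Ccl22. Cholesterol synthesis was higher for 9 of 13 genes, 10 adjusted over the list alone (adjusted p = 1.19e-07; adjusted p = 0.337 with an estimated correlation). Cell cycle genes were higher for 14 of 28, 20 adjusted over the list alone (adjusted p = 2.63e-07; adjusted p = 0.616 with an estimated correlation). Stress genes were lower for 11 of 19 and higher for 3, by either adjustment (adjusted p = 3.55e-05; adjusted p = 0.569 with an estimated correlation), and 7 were lower without naive control 1. T cell markers were lower for 9 of 9 (adjusted p = 1.03e-11; adjusted p = 0.337 with an estimated correlation) and NK cell markers for 8 of 9 (adjusted p = 2.32e-08; adjusted p = 0.337 with an estimated correlation), each by either adjustment. In total 3986 genes passed, 2352 higher and 1634 lower in YFP control, with 2020 passing under array weights and 1537 with only the 2 groups. The change with CD40 activation and this difference share the naive arrays. Their log2 changes correlated across genes with r = 0.584, and in simulated data with no change, where only the shared arrays link them, with r = 0.497. The covariance was 0.227 in the data and 0.0233 in the simulated data.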

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

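The tests of explanations given in this part were chosen only after the results were seen, whereas the difference of changes was planned. With LMP1 and with CD40 activation, 229 genes were called in opposite directions, and the difference passed for each of them. That adds no separate support, since changes of opposite sign add up in the difference. Of the 229 genes 76 were up with LMP1 (213.2 expected of independent lists) and 153 down (197.1 expected). Among members of the fixed gene lists, those down with LMP1 and up with CD40 activation differed by -7.06 (S1pr3), -4.98 (Bhlhe41), -4.80 (Myof), -4.69 (Havcr1), -3.78 (Ighg3), -3.46 (Ccr6), -2.54 (Egr3), -2.33 (Lgmn) and -2.01 (Bcl2l11). Those up with LMP1 and down with CD40 activation differed by 1.43 (Tap2), 1.56 (Pdk1), 1.77 (Pmaip1), 2.18 (Tnfrsf14), 2.81 (Ikbke), 2.88 (Il5ra), 2.93 (Junb), 2.96 (Atf3), 3.87 (Dusp1), 6.44 (Jun) and 8.51 (Hspa1b). Hspa1b and S1pr3 differed between YFP control and naive control in the same direction and by similar amounts as with CD40 activation. Their opposite changes cannot be told apart from what separates the controls. Without YFP control 2 the difference for Jun was 5.03, and its change with LMP1 did not pass (0.88). Of 3124 probe sets with no or several gene symbols, which the comparisons did not use, 620 changed with LMP1 (306 up, 314 down) and 443 with CD40 activation (242 up, 201 down).

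Markers of T, NK and red cells were higher in naive control than in CD40-activated cells. Both groups share array set, strain and sex, so by design these could not produce the pattern and were not tested. The T cell list differed between the groups by a median of -2.67 log2 (SD 0.67 over its genes). On naive control 1 and 2 the list medians were 8.22 and 8.07 (T cell), 6.97 and 6.39 (NK cell) and 7.69 and 7.09 (erythroid and platelet). The median genes of these arrays were at 5.69 and 5.75. Transcripts that mark other cells were thus present in the uncultured preparation, although CD43 depletion removes most T and NK cells. Whether culture removed such cells or only their transcripts cannot be told apart, since the value of -2.67 is the pattern itself and no other test was made. The genes concerned reached 9.65 and 9.51 (Cd3g) and 9.96 and 9.39 (Cd3e) on the naive arrays, and of the 9 T cell genes 0 stood on another list and 3 lay above the array median on both LMP1 arrays. A loss of these cells during culture was not tested.

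Of 69 small nucleolar RNA genes, a family chosen after seeing the data, 38 were lower and 4 higher in LMP1 than in CD40-activated cells (adjusted p = 1.34e-15; adjusted p = 0.196 with an estimated correlation), and 54 were lower and 2 higher in YFP control than in naive control (adjusted p = 2.94e-35; adjusted p = 0.237 with an estimated correlation). Culture for 2 days as the whole cause is argued against, since LMP1 and CD40-activated cells were both cultured and 38 genes passed as lower between them, with a median of -1.12 (SD 1.47 over the genes). Culture could be part of it, since the median was -0.91 (SD 0.83) between CD40-activated and naive cells of the same set. Those groups also differed in the antibody against CD40 and in markers of T, NK and red cells, so culture cannot be told apart from these. A difference in RNA preparation or arrays between the sets (median -2.19 between YFP control and naive control) cannot be told apart from strain, sex, TAT-Cre, sort and 2 days of culture, which all differ between these groups. The YFP controls themselves differed by a median of -0.60 over these genes and the naive controls by -0.05.

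YFP control 2 stood apart from YFP control 1, higher by more than 1 log2 at 285 genes and lower at 665. An LMP1 array under the wrong label is argued against, since over the 1083 genes at least 1 log2 higher in LMP1 than in CD40-activated cells the median of YFP control 2 minus 1 was -0.02 (SD 0.56 over the genes), against 1.25 for LMP1 minus YFP control 1. A compressed intensity range as the whole cause is argued against because a smooth curve in intensity took 18.9% of the variance of the difference. Added monocytes and macrophages as the cause of the lower genes are argued against, since they would lower B cell genes alike and the B cell identity median was -0.37 (SD 0.38), with 1 of 15 genes lower by over 1 log2. As a cause of higher genes they stay open, since their list (median 0.31, SD 0.36) had 4 of 12 genes above the array median and Il1a (2.79), Fpr2 (2.27), Ly96 (2.21), Ccl2 (2.15), Wfdc17 (1.81) and Lyz2 (4.91 and 5.90) were higher on YFP control 2. The lung transcripts Scgb1a1 (4.28 and 7.80), Sftpc (5.25 and 7.20), Sftpa1 (5.24 and 6.30) and Sftpb (5.24 and 6.15), chosen after their values were seen, were higher on YFP control 2, and lung RNA might be present in it. Over the other 10 genes of a lung list the median was 0.23 and 8 were higher. These cannot decide the question, since Napsa lay at 9.51 or above on all 8 arrays and others lay low, such as Bpifa1 (3.44 and 3.97 on the YFP controls). Of all 14 lung genes 4 lay above the array median on both LMP1 arrays and 0 stood on another list. The reporter sort would remove such cells, which does not bear on RNA that entered after it. A difference between the animals or cultures behind the arrays was not tested.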

How the results depend on the processing

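Leaving out YFP control 2 and naive control 1 together, and the list tests without them or under quantile normalization within sets, were chosen after seeing the data, and the other alternatives were planned. Of 586 named results past the threshold, 584 kept direction and call with trend and robust fitting, 564 with array medians subtracted, 567 with quantile normalization within sets, 577 with a replicate block and 565 with array weights, and 439 of 479 did with only the 2 groups compared. Leaving out single arrays kept between 496 and 580. Counts of changed genes stayed within 1.5 times under these settings, except as follows. The main model used 1 spread per gene for all 4 groups, although replicates differed unequally. The SD of their difference was 0.201 for LMP1, 0.242 for CD40-activated, 0.376 for naive control and 0.474 for YFP control. With only the 2 groups compared, LMP1 against CD40-activated gave 6360 genes (main 3191) and YFP control against naive control 1537 (main 3986). With array weights these were 6751 and 2020. Against these groups' own spread the main counts are thus low for the first pair and high for the second. Other causes were not tested. For the first pair, leaving out YFP control 2 and naive control 1 gives the same fit. Leaving out YFP control 2 and naive control 1 gave 7146 genes for CD40 activation, 6360 for LMP1 against CD40-activated, 3543 for the difference of changes and 2867 shared by both responses. Leaving out each array in turn gave 2647 to 7090 genes for LMP1 against YFP control, 1576 to 5631 for CD40 activation, 1275 to 4735 for LMP1 against CD40-activated, 707 to 4199 for the difference of changes, 2695 to 5955 for the controls and 881 to 2580 for the shared genes. The lowest counts came without an LMP1 or a CD40-activated array, whose replicates lay closest, except for the controls, where the lowest came without naive control 2. Without a YFP control array, whose pair lay farthest apart, counts were higher except for YFP control 2 in LMP1 against YFP control (4732) and in the controls (3719). Camera called 17, 14, 17, 20 and 9 of 33 lists in the 5 comparisons in their order and 0 in each with an estimated correlation, and fry called 23, 22, 21, 20 and 11. No list reversed its camera direction among those called under these settings. Among named genes, Mcl1 moved from -0.10 to 0.56 with LMP1 without YFP control 1 and to -0.76 without YFP control 2, and passed in both. Without YFP control 2 and naive control 1, Cd37 came to -0.48 with LMP1, from about 0, and Cdt1 to 0.77 between the controls, and both passed. Replicate numbers carried no sign of pairing, with correlations of their deviations across genes between -0.102 and 0.0744, and with a replicate block the counts were 4923, 3659, 3036, 1672 and 3807. Signal near background limits what can be seen of dim genes. The difference of changes had no fit with only the 2 groups, since it needs all 4.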

Other observations

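Among 24 gene families examined after seeing the data, genes of serine, one-carbon and amino acid synthesis stood out with LMP1. Since the families were chosen with the results in view, their p-values describe the data and are not an independent test. Of 15 members 14 rose and 0 fell against YFP control (adjusted p over the families = 7.57e-13; adjusted p = 0.0316 with an estimated correlation), among them Asns (3.38), Cth (3.09), Shmt2 (3.08), Psat1 (2.85), Phgdh (2.33) and Mthfd2 (1.99). With CD40 activation 10 rose and 0 fell (adjusted p = 4.82e-07; adjusted p = 0.11 with an estimated correlation), with Psat1 at 2.51 and Asns at -0.05, and 10 were higher in LMP1 than in CD40-activated cells (adjusted p = 8.13e-10; adjusted p = 0.0534 with an estimated correlation). Proteasome subunits rose for 33 of 39 genes with LMP1 (adjusted p = 4.37e-15; adjusted p = 0.147 with an estimated correlation) and 25 of 39 with CD40 activation (adjusted p = 2.63e-10; adjusted p = 0.177 with an estimated correlation). Aminoacyl-tRNA synthetases rose for 24 of 32 genes and fell for 1 with LMP1 (adjusted p = 1.08e-12; adjusted p = 0.148 with an estimated correlation), and rose for 15 with CD40 activation (adjusted p = 5.59e-06; adjusted p = 0.218 with an estimated correlation). The signs of these family medians were kept with array medians subtracted and with quantile normalization within sets.

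The interferon-activated p200 family fell for 7 of 10 genes with LMP1 (adjusted p = 3.41e-08; adjusted p = 0.0555 with an estimated correlation), led by Ifi214 (-5.77) and Ifi209 (-4.33), and for 4 with CD40 activation (adjusted p = 0.00173; adjusted p = 0.173 with an estimated correlation). Guanylate-binding proteins rose for 5 of 10 genes with LMP1 (adjusted p = 0.0278; adjusted p = 0.151 with an estimated correlation) and fell for 4 with CD40 activation (adjusted p = 0.00563; adjusted p = 0.175 with an estimated correlation), with Gbp2b at 3.50 and, without passing, 0.76. Immunity-related GTPases were higher in LMP1 than in CD40-activated cells for 6 of 8 genes and lower for 1 (adjusted p = 6.71e-07; adjusted p = 0.0607 with an estimated correlation), with Igtp at 3.32 and Iigp1 at 2.83. They gave no call with LMP1 against YFP control (3 of 8 up; adjusted p = 0.193), and YFP control was higher than naive control for 5 of 8 and lower for 1 (adjusted p = 0.0195; adjusted p = 0.265 with an estimated correlation). Toll-like receptors fell for 6 of 12 genes and rose for 1 with LMP1 (adjusted p = 0.00278; adjusted p = 0.147 with an estimated correlation), with Tlr7 at -2.81, Tlr9 at -2.12 and Tlr4 at -1.22. The same genes Tlr7 (2.06), Tlr9 (1.25) and Tlr4 (0.72) rose with CD40 activation, where the family as a whole gave no call (adjusted p = 0.717) and its median changed sign when array medians were subtracted (from -0.09 to 0.02). The family was higher in YFP control than in naive control for 4 of 12 genes (adjusted p = 0.0195; adjusted p = 0.265 with an estimated correlation). Directly in LMP1 against CD40-activated cells 2 were higher and 3 lower, without a call (adjusted p = 0.0978). Immunoglobulin V segments fell for 7 of 8 genes with LMP1 (adjusted p = 1.46e-05; adjusted p = 0.222 with an estimated correlation) and rose for 4 with CD40 activation (adjusted p = 0.00186; adjusted p = 0.383 with an estimated correlation). YFP control was already higher than naive control for 7 of 8, and directly LMP1 cells were lower than CD40-activated cells for 2 of 8.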
